A study of Oryza sativa with 2 samples.

How the data were processed

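Total RNA came from seedlings of 1 control and 1 salinity sample, grown for 14 days at 0 and 6 dS/m. Per the labels' protocols, 800 ng of RNA per sample was enriched for poly(A) transcripts and made into libraries with a NEBNext Ultra II kit. Per the submitters' processing notes, the authors used FastQC, MultiQC, STAR, featureCounts and DESeq2. The versions, the genome build, the annotation and the counting options are not given in the sources used here. The deposited table holds whole-number counts per gene model with the exon positions and the exon length in bases. Coordinates below are those of the deposited table.

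The salinity column holds no odd count, and 29.15% of control and 70.56% of salinity values above 0 are multiples of 4. Even counts in excess can arise when both mates of a read pair are counted one by one. Why the salinity column is even throughout is not given in the sources used here. An interval from counts that repeat the same molecule is too narrow, so a read-pair scale was added after seeing the data. It divides control counts by 2 and salinity counts by 4. The scale is inferred from the values and is approximate, since 11654 control values above 0 are odd. Printed intervals use it, while calls by the size rule use the counts as deposited, as set out before the data were examined, with the calls on the read-pair scale given beside them. In units of 1e6, the totals of 45.36 control and 15.03 salinity counts are 22.68 and 3.76 read pairs on that scale.

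Library sizes were scaled with TMM factors from edgeR 4.0.16 in R 4.3.3 over gene models with at least 10 counts in both libraries together. The log2 ratio is that of scaled counts with a prior count of 0.5 per library. Its 95% interval is the exact conditional binomial interval (Clopper-Pearson) of the salinity share of a gene's counts. A gene was called higher or lower when the whole interval lay beyond 2-fold. With 1 library per group these calls compare the libraries, not the conditions. PCR reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. For genes at 0 counts the floor was 3 read pairs, which is 6 control counts (0.121 CPM) or 12 salinity counts (0.872 CPM). The plan had named 3 counts, and the wider floor was chosen after the values were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the remaining steps.

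The 15 gene lists were written from general knowledge of rice loci before the data were examined. Other planned lists, which needed gene descriptions, were not analysed here. Each list's median was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. Random members were drawn singly, so a percentile does not allow for listed neighbours, such as the RAB16 genes, that may change together. Lists with fewer than 5 measured members have no percentile. The deposited table does not pair its locus identifiers with names, and the name table used here (assembly ASM3414082v1) does not carry those identifiers. Each of the 164 hand-written pairs of name and locus was therefore checked by name, chromosome, gene order and span, with a tolerance of 25%. For 110 loci the name was found in the same place, 9 were dropped, and 45 names were not in the table. SOS1, NHX1, NHX2, NHX3, NHX5, SNAC1, WSI18, ProDH, bZIP72, CATC, GR3, RBCS4, LHCA3, PSBR1, NiR, NCED1, NCED4, NCED5, PR1b and WRKY45 are among the 45, and their names rest on the hand-written list alone. The rules of this check, the accepted synonyms and the decision not to name 3 genes with an ambiguous match, which stay in the list counts and medians, were chosen after the values of listed genes had been seen.

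Named genes follow a rule set before the data were examined. It takes the 15 genes per direction with the largest conservative ratio among named genes with at least 100 counts, up to 4 members per list past the size rule, a fixed set of salt-related and reference genes, and the 5 most abundant genes per library. Because only listed genes have names, the first part could draw on listed genes alone. Members named to complete a count of 5 or fewer, WRKY45, and the genes given as within the range outside the fixed set were chosen after their values were seen. UBQ5, a planned reference gene, was among the dropped loci, and 1 other planned reference gene is not reported here. In the whole table, 1645 gene models share exon bases, and reads of near-identical copies, such as the RAB16, Rubisco small-subunit and aquaporin genes, may have been split between them or lost. Strand use in counting is not given in the sources used here.

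The procedure was tested on simulated counts for the 26638 genes of the salinity and control comparison, with 200 changed genes. As deposited, 91.0% of 100 genes changed 4-fold and 100.0% of 100 changed 8-fold were recovered, and 2 of 26438 unchanged genes were called. On the read-pair scale, 79.0% and 94.0% were recovered. The simulated counts were independent Poisson draws, without repeated counts of a molecule or variation between seedlings. The share of unchanged genes called therefore says little about false calls in the deposited counts. Of 100 random lists of 10 unchanged genes, 5 lay outside the middle 95% of random lists. Alternatives covered DESeq2 1.42.0 size factors, total counts, upper-quartile factors, count filters, the size rule and the 50 most abundant genes. They also covered a control library thinned to the salinity depth in deposited counts, the prior count and the matching of random lists.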

Results

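Messenger RNA was sequenced from 14-day rice seedlings of the cultivar CARI Dhan 7. Seeds had germinated either in distilled water (control) or in a mixed salt solution with an electrical conductivity of 6 dS/m (salinity). Each group had 1 library, so no difference below has a replicate check, no p-value is given, and every interval covers counting error only. The control library held 45359020 counts and the salinity library 15031328. All 26437 salinity values above 0 were even, against 61.73% of the control values above 0. The intervals below therefore use a read-pair scale, inferred from these values, with 2 control counts or 4 salinity counts taken as 1 pair. Of 55986 gene models in the deposited table, 30451 had a count in the control library and 26437 in the salinity library.

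The comparison asks which transcripts differed in abundance between the seedlings raised in saline solution and those raised in water. In the salinity library, 5 of 8 dehydration-related genes, among them late embryogenesis abundant (LEA) and dehydrin genes, were higher. So were 7 of 10 genes of abscisic acid (ABA) metabolism and signalling (6 with total counts or on the read-pair scale). Of 15 sodium and potassium transport genes, 4 were higher, among them the sodium transporter genes HKT1;1, HKT1;5 and NHX1, and 1 was lower. Of 11 genes for diterpenoid phytoalexins and other defence, 10 were lower. LEA3-1, a LEA protein gene, stood at 61.84 CPM (counts per 1e6 scaled counts) in the control and 6649 CPM in the salinity library, 107.5-fold higher. That was the highest ratio among the listed genes only. Gene models outside the lists rose more, such as LOC_Os03g51920, from 4.58 CPM in the control to 987.1 CPM in the salinity library, 214.9-fold higher. The alpha-amylase gene AMY1A had 68861 counts in the control and 0 in the salinity library, at least 1595-fold lower.

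Over the 26638 gene models with at least 10 counts in both libraries together, 2831 were higher and 2755 lower in the salinity library by the size rule, the whole 95% counting interval of the ratio lying beyond 2-fold. The remaining 21052 were within that range or its counting error. On the read-pair scale the counts were 2073 higher and 1404 lower. The lower genes made up 49.3% of the calls with the TMM scaling used here and 64.6% with total-count scaling, which moved the median log2 ratio of all genes by -0.25. That median was -0.08 with TMM, and list medians below are given relative to it. Across genes, which are not independent replicates, log2 CPM in both libraries had a Pearson correlation of 0.889.

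Dehydration-related genes included the highest ratio of any list. Of 8 measured members, 5 were higher, 1 was lower and 2 were within the range, and the list median of 3.16 stood above all 10000 random lists matched on expression (percentile 100.0). LEA3-1 (LOC_Os05g46480, chromosome 5, 26927607 to 26928902) had a log2 ratio of 6.75, with an interval of 6.67 to 6.82. The dehydrin genes RAB16A, RAB16B and RAB16C are the 3 measured models of 4 on chromosome 11 between 15327768 and 15343857, and all 3 were higher, with log2 ratios of 5.56, 5.20 and 3.07. RAB16A (LOC_Os11g26790) went from 112.2 CPM in the control to 5298 CPM in the salinity library. The fifth higher member was WSI18, at 3.08. EMP1, an LEA gene of the embryo, was lower at -2.58 (interval -3.51 to -1.81), and LEA3-2 was within the range at 0.83. SalT, a lectin gene named for its response to salt, was at 297.8 CPM in the control and 284.6 CPM in the salinity library, a log2 ratio of -0.07 (interval -0.16 to 0.03).

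Genes of ABA metabolism and signalling were higher in 7 of 10 measured members and lower in 0, with a list median of 3.22 (percentile 100.0). NCED3 (LOC_Os03g44380, chromosome 3, 24959107 to 24961777), which encodes an enzyme of ABA synthesis, had 8.32 CPM in the control and 83.43 CPM in the salinity library, a log2 ratio of 3.32 (interval 3.06 to 3.59). The protein phosphatase genes PP2C68, PP2C30 and PP2C49 had log2 ratios of 5.34, 4.67 and 3.44. The further ABA synthesis genes NCED4 and NCED5 were higher at 4.93 and 1.57, and the NCED5 call was lost with total counts, with the control library thinned and on the read-pair scale, which leaves 6 of 10 higher in each. ABA8ox3, which encodes an ABA-degrading hydroxylase, was higher at 2.94, whereas NCED1 was within the range at 0.70 and ABA8ox1 was at 525.3 CPM in the control and 535 CPM in the salinity library.

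Sodium and potassium transport genes had a list median of 0.82 (percentile 99.3), with 4 of 15 measured members higher, 1 lower and 10 within the range. With total counts 3 members were higher and 2 lower. HKT1;1 and HKT1;5, which encode sodium transporters, had log2 ratios of 4.39 (interval 4.10 to 4.70) and 3.08 (interval 2.62 to 3.55). The other listed HKT genes were within the range, HKT1;3 at 1.53, HKT1;4 at -1.62 and HKT2;1 at -0.79. HKT1;5 (LOC_Os01g20160, chromosome 1, 11458955 to 11463442) rested on 146 control and 344 salinity counts. NHX1, a vacuolar sodium/proton antiporter gene, was at 3.29 (interval 3.12 to 3.45), whereas NHX2, NHX3 and NHX5 were within the range at 0.13, 0.61 and 0.15. The kinase gene CIPK24 was higher at 1.27, a call lost with total counts and on the read-pair scale. SOS1, the plasma-membrane sodium/proton antiporter gene, stayed within the range at 0.73 (interval 0.55 to 0.91). HAK5, a high-affinity potassium transporter gene, was lower at -2.81 (interval -4.74 to -1.48) on 16 salinity counts.

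Of 8 osmoprotectant genes, 2 were higher and 2 lower, with a list median of -0.02 (percentile 35.03). Both genes for proline synthesis, P5CS1 and P5CS2, were higher, with log2 ratios of 1.67 (interval 1.56 to 1.79) and 2.73 (interval 2.46 to 3.002). P5CS2 and TPP1 share exon bases with another gene model. ProDH, which encodes the first enzyme of proline breakdown, was lower at -1.43 (interval -1.79 to -1.09). The trehalose phosphatase gene TPP1 was lower at -1.53, and its call was lost on the read-pair scale.

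Stress-related transcription factor genes were higher in 5 of 11 members and lower in 0, with a list median of 1.17 (percentile 99.8). The NAC genes NAC6, NAC5 and SNAC1 had log2 ratios of 2.19, 1.97 and 1.09, and the bZIP genes bZIP72 and bZIP23 were at 2.11 and 1.99. The SNAC1 call was lost with total counts. DREB2A was within the range at 0.94 (interval 0.61 to 1.26) and shares exon bases with another gene model. Nitrogen and sulfur genes had 5 of 11 members higher and 0 lower, with a list median of 1.09 (percentile 99.3). These were the nitrate transporter gene NRT2.3 (2.25), the nitrite reductase gene NiR (2.19), the nitrate reductase gene NIA1 (1.83), the glutamate synthase gene FdGOGAT (1.64) and the ammonium transporter gene AMT1;1 (1.46). All are nitrogen genes. APR1, the sulfur gene of the list, was within the range at -0.66 (interval -0.95 to -0.38).

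Photosynthesis genes were mostly within the range, 22 of 26 measured members, with 3 higher, 1 lower and a list median of 0.59 (percentile 94.99). RBCS2, a small-subunit gene of Rubisco, was the most abundant transcript of the salinity library at 16150 CPM and had 8005 CPM in the control. Its log2 ratio of 1.01 (interval 0.999 to 1.03) lay at the edge of the size rule, and the call was lost with total counts, with upper-quartile factors and on the read-pair scale. RBCS4 and LHCA3 were higher at 1.41 and 1.24, and the LHCA3 call was lost with total counts. PSBR1 was lower at -4.38. CAB2R, the most abundant transcript of the control library, was at 8607 CPM there and 8605 CPM in the salinity library. CAB1R was at 6749 CPM and 11520 CPM, and LHCB2 at 6138 CPM and 7819 CPM. Of the unnamed models among the 5 most abundant of the salinity library, LOC_Os07g10840 was at 245.7 CPM in the control and 9237 CPM under salinity, and LOC_Os11g07020 at 2494 CPM and 9404 CPM. A further unnamed model, among the 5 most abundant of both libraries, was at 4850 CPM and 11120 CPM.

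Aquaporin genes were higher in 3 of 14 members and lower in 0, with a list median of 0.75 (percentile 96.4). TIP1;2, PIP1;3 and PIP1;2 had log2 ratios of 2.49, 1.43 and 1.24, and the PIP1;2 call was lost with total counts. PIP2;1 was within the range at 0.33. Among 17 antioxidant genes, 3 were higher, 1 was lower and 13 were within the range, with a list median of 0.35 (percentile 75.2). With APX5, at 16 control and 0 salinity counts, set to its bound, the median was 0.46. That bound lies above no change. With at least 50 counts per gene, which leaves APX5 out, the median was 0.41. Catalase genes went different ways. CATC was higher at 2.98, CATA lower at -1.14, and CATB was at -0.02 (interval -0.12 to 0.07). The ascorbate peroxidase gene APX8 was higher at 1.59. The glutathione reductase gene GR3 was higher at 1.43, a call lost with total counts, with upper-quartile factors and on the read-pair scale.

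**Figure D1:**
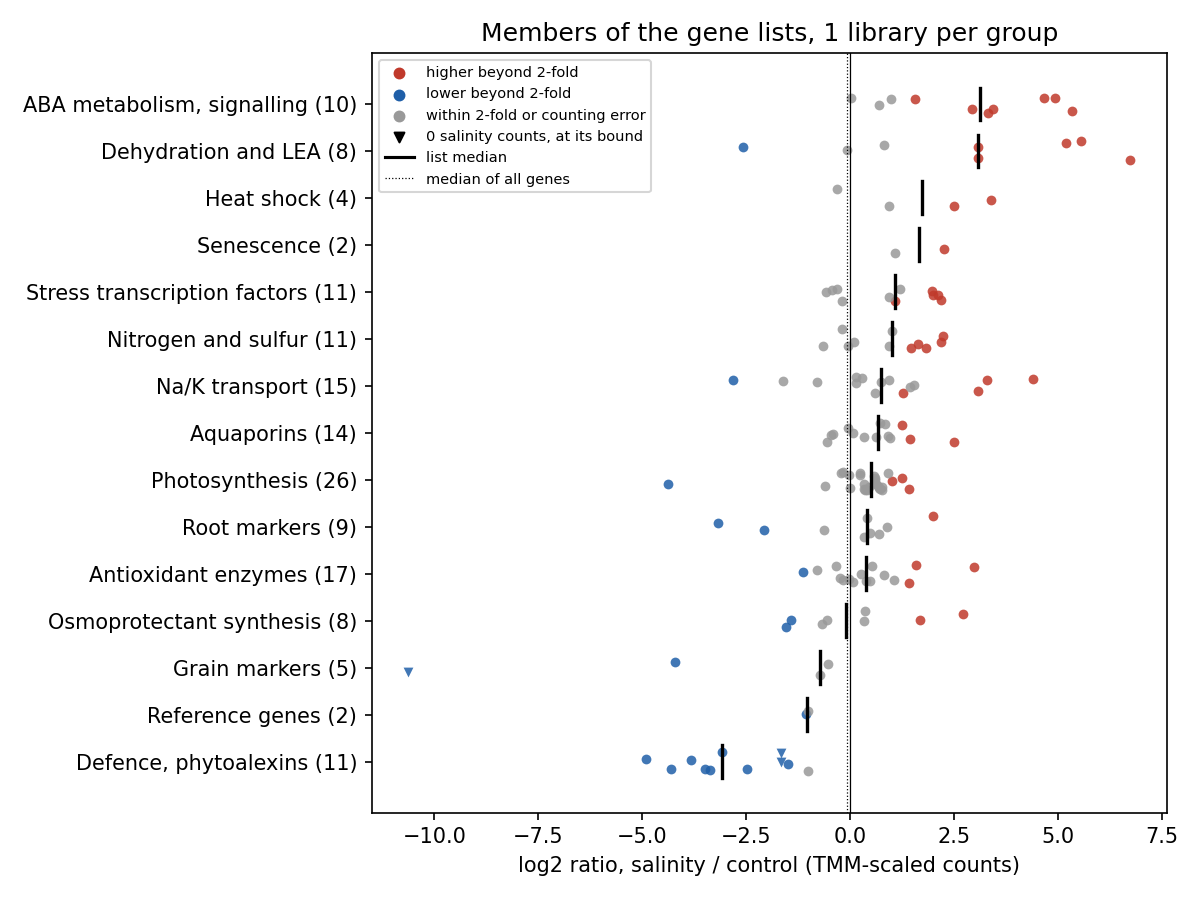
Log2 ratio of salinity to control (horizontal axis, TMM-scaled counts) for each measured member of the 15 gene lists, 1 point per gene and 1 library per group. Colours give the size rule, and the dotted line is the median of all genes at -0.08. The black bars are list medians, and triangles are genes with 0 salinity counts drawn at their bound. The bars use those bounds too, also for 2 members not drawn because their bound lies above no change.

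Defence and phytoalexin genes were lower in 10 of 11 measured members. With the 2 members at 0 salinity counts, KSL4 and PR1b, set to their bound, the list median was -2.999. With fitted ratios it was -3.41 and lay below all 10000 random lists (percentile 0.0). Several members are neighbours on a chromosome, which the random lists do not allow for. CPS4, CYP99A3, MAS1, KSL4 and CYP99A2, genes of momilactone synthesis, lie between 5318060 and 5486773 on chromosome 4. That stretch holds 26 gene models, of which 6 were measured and 6 were lower. Its summed level was 126.8 CPM in the control and 9.88 CPM in the salinity library, 12.8-fold lower. CPS4 (LOC_Os04g09900) had a log2 ratio of -4.32 (interval -5.66 to -3.30), and CYP99A3 and CYP99A2 were at -3.36 and -3.49. KSL4 had 136 control counts and 0 salinity counts, at least 3.15-fold lower. On chromosome 2, between 21765009 and 21847837, 3 of 4 measured models were lower, namely CPS2 at -4.90 (interval -6.82 to -3.58), KSL7 at -1.50 (interval -1.79 to -1.22) and LOC_Os02g36190. The last had 875 control counts and 8 salinity counts, which is under the floor, and a log2 ratio of -4.84 (interval -7.98 to -3.06). The pathogenesis-related gene PBZ1 was lower at -3.83 (interval -4.46 to -3.27). WRKY45, at -1.002, was the member within the range, and with total counts 11 of 11 members were lower.

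**Figure D2:**
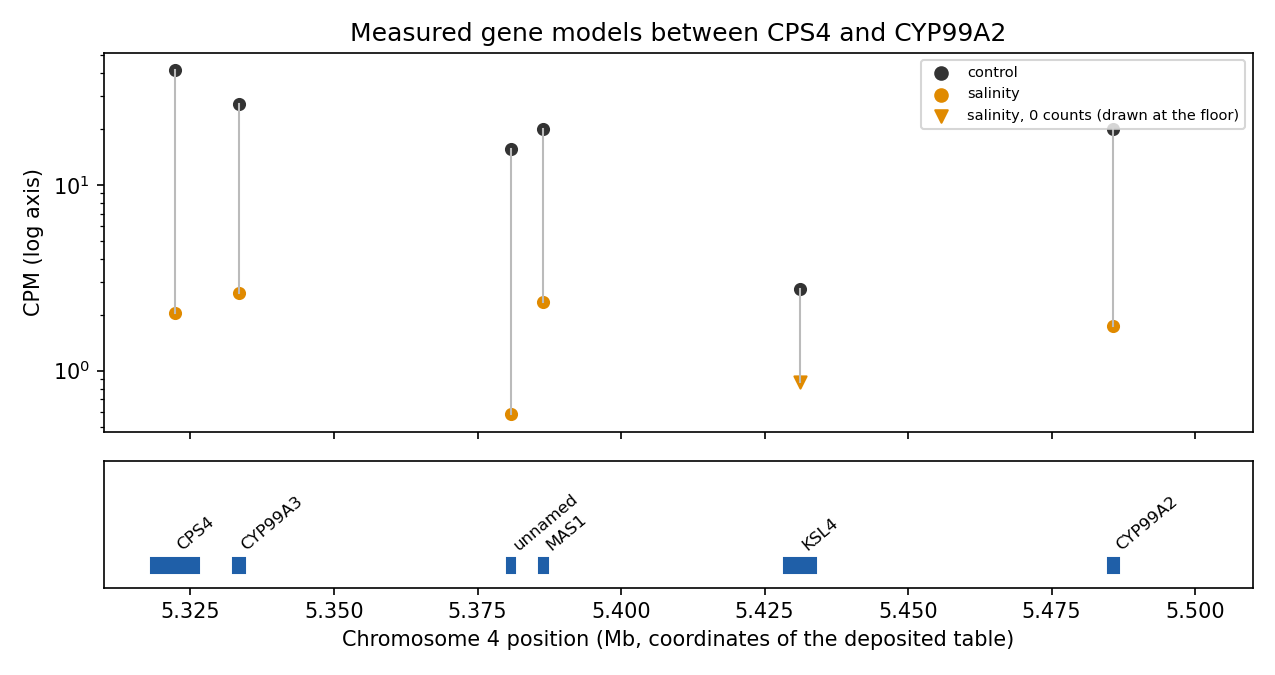
TMM-scaled CPM (vertical log axis) of the 6 measured gene models between CPS4 and CYP99A2 on chromosome 4 in the control (dark) and the salinity library (orange), above the position of each model in Mb. All 6 models are lower in the salinity library; the triangle marks KSL4, with 0 salinity counts, at the floor of 0.872 CPM, and the unnamed model, with 8 salinity counts, is drawn at 0.581 CPM, under that floor.

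Most markers of other seedling parts were within the range. Of 9 root markers, 1 was higher, 2 were lower and 6 were within the range, with a list median of 0.48 (percentile 83.9). The lower ones were the nicotianamine synthase genes NAS1 (-3.19) and NAS2 (-2.07), and the higher one was the nitrate transporter gene NRT2.1 (1.99). Lsi1, a silicon transporter gene of roots, was at 0.48 (interval 0.41 to 0.56). Of 5 grain markers, 2 were lower, AMY1A (LOC_Os02g52710, chromosome 2, 32248279 to 32250180) and AMY3E at -4.21 (interval -6.13 to -2.89). AMY3D was at -0.72 and the glutelin gene GLUA2 at -0.53, both within the range. The fitted median of this list, -3.36 (percentile 0.08), became -0.64 with genes at 0 counts set to their bound. For the glutelin gene GLUA1, with 19 control counts, that bound lies above no change. With at least 50 counts per gene, which leaves GLUA1 out, the fitted median was -2.38. Heat shock genes had 2 of 4 members higher, HSP101 at 3.39 and HSP26.7 at 2.501, and a list median of 1.80. NYC1, a gene of chlorophyll breakdown, was higher at 2.25, and SGR, the other member of that list, was at 1.09, with a list median of 1.75.

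Of 2 reference genes, 1 was lower and 1 was within the range, with a list median of -0.96. ACT1 was lower at -1.07 (interval -1.18 to -0.95), a call lost with DESeq2 size factors, with the control library thinned and on the read-pair scale. GAPDH was at -1.02 and passed the size rule as lower with total counts and upper-quartile factors.

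**Figure D3:**
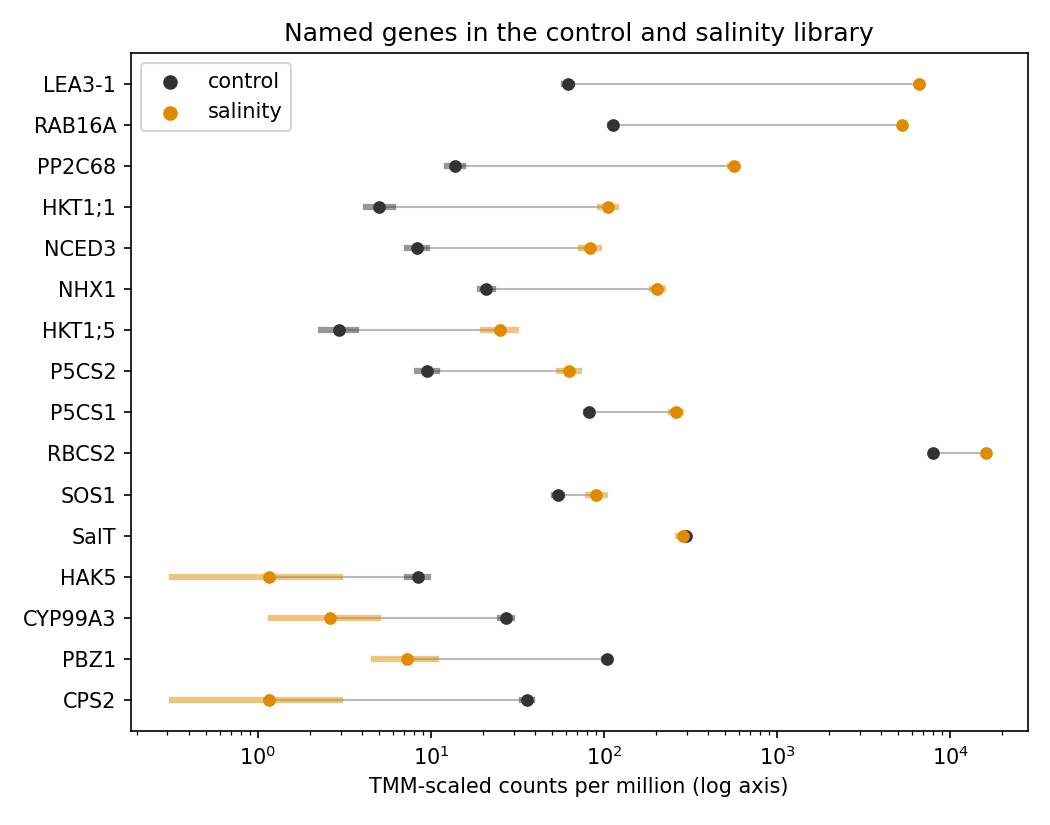
TMM-scaled CPM (horizontal log axis) of 16 named genes in the control (dark) and the salinity library (orange), 1 library each; thick bars are 95% exact Poisson counting intervals on the read-pair scale. LEA3-1 spans the widest distance, from 61.84 to 6649 CPM, while the SalT points overlap.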

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

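The read-pair scale, the ratios relative to the median of all genes, the restriction to models of at least 1000 bases and the restrictions of list membership were chosen after seeing the data. Under 13 alternatives, the counts of 2831 higher and 2755 lower genes stayed within 1.5 times their value except with another size rule or on the read-pair scale. By construction, an interval beyond 4-fold left 1053 higher and 837 lower, an interval beyond 1.5-fold gave 4558 and 4988, and a point estimate of 2-fold without an interval gave 4322 and 5556. On the read-pair scale 2073 were higher and 1404 lower, each of them among the genes called from the deposited counts, because the scale widens the intervals. Total-count scaling gave 2180 higher and 3970 lower. List medians relative to the median of all genes cannot move with the scaling or with the matching of random lists, which fixes 75 of their values. Under 5 other alternatives, 74 of 75 medians lay inside a reference range. That was the nominal 95% order-statistic interval of the reported median, or the members' range for lists with fewer than 5 members. The exception was the median of the 2 reference genes on the read-pair scale, -0.99 against -0.96, where the cause was not tested. Those intervals are wide. For the lists of 5 and 8 measured members they span all members, so those medians could hardly leave them. The grain marker median, of such a list, ran from -3.36 to -1.50. Lists that lost no member under a restriction of membership kept their median by construction, such as aquaporins with 14 of 14 members under both restrictions. Percentiles ran from 82.5 to 98.4 for photosynthesis, from 28.8 to 72.4 for osmoprotectants and from 40.4 to 82.1 for antioxidant enzymes, whose median was 0.06 with members found in the name table alone. No called value among 68 genes changed sign under 6 alternatives. That was nearly certain in advance, because called ratios lie beyond 2-fold and the scalings moved the median log2 ratio by only -0.25 to 0.03. The prior count does not enter the calls, so that alternative could not change them. Under the other alternatives, 10 of the 68 genes changed their call in at least 1. These were TPP1, CIPK24, RBCS2, PIP1;2, ACT1, SNAC1, GAPDH, NCED5, GR3 and LHCA3. Listed members within the range and outside the fixed set were not among the 68, and some of them passed the size rule elsewhere. With total counts, for instance, 11 of 11 defence and phytoalexin genes were lower. With the control library thinned to the salinity depth in deposited counts, 2594 were higher and 2454 lower. Of these, 2508 and 2378 were called from the full counts. On the read-pair scale that is not equal depth, since a control pair takes 2 counts and a salinity pair 4. Matching on GC content was not run because no genome was used, organelle genes could not be left out because the table holds nuclear models, and the hand-written members were already the whole lists. No paired analysis was possible because each group has 1 library.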

Other observations

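All tests of explanations below were chosen after the results were seen. Neighbouring genes often shared a call. On chromosome 4, 10 adjacent measured gene models between 7024800 and 7166406 were all higher in the salinity library by the size rule, with a summed level of 8.02 CPM in the control and 111.2 CPM under salinity. Of these, 2 were under the floor in both libraries, 1 of them with 0 control counts, and the other 8 had log2 ratios from 2.35 to 7.15. On the read-pair scale 9 of the 10 kept the call. The longest lower stretch was the 6 models of the diterpenoid region on the same chromosome. In 1000 shuffles of the calls within chromosomes, the longest stretch of either direction was 7, so the higher stretch is longer than any of them and the lower one is not. Stretches of at least 4 models numbered 22, against a median of 6 and a highest of 15 in the shuffles.

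There were 594 lower genes with 0 salinity counts and 127 higher genes with 0 control counts, in libraries that differ in depth. In the highest quartile of expression, gene models under 1000 bases had a median log2 ratio of -0.43 and those of at least 2000 bases 0.19. In the lowest quartile the medians were -0.33 and -0.38, and the shorter models had the lower median in the 2 upper quartiles only.

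AMY1A and its neighbour LOC_Os02g52700, with 3974 control counts, both had 0 salinity counts. Models elsewhere and outside the lists did too, such as LOC_Os02g44320 with 20292 control counts and LOC_Os01g14850 with 14388. Depth is argued against, since 19137 salinity counts of AMY1A would be expected at its control share. Grain tissue present only in the control sample stays open, because 2 of the 4 grain markers with at least 100 control counts were not lower beyond the size rule and the list is too short to decide. A loss of the DNA of the amylase pair also stays open, although the nearest models with enough counts had 546 salinity counts where 573 were expected on the left and 352 where 89 were expected on the right. Together they bound any such loss to 48.7 kb; an effect of salinity is untested with 1 library per group.

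The lower defence and phytoalexin genes may reflect salinity, as a hypothesis that 1 library per group cannot test. A lower root share is argued against, since 2 of 9 root markers were lower by at least as much as KSL7, the called defence gene nearest to 0. Choice among the 4 scalings tried is argued against too, because the weakest list median over them, here not centred on all genes, was -3.46. The scalings moved the median of all genes by only -0.25 to 0.03, so the size of the ratios fixed this outcome.

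The even salinity counts concern every interval. If both mates of each pair had been counted 1 time, halved counts would be whole pairs and about 50% of the large ones would be odd. Of 10687 halved counts of at least 100, 35.3% were odd (95% exact binomial interval 34.4 to 36.2), which argues against that as the only cause. In the control column, 42.4% of counts of at least 100 were odd. What else made the salinity column even stays open, and no biological explanation was tested.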
